A study of Drosophila melanogaster with 2 samples.

How the data were processed

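Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in whole Drosophila melanogaster embryos of mixed sex, aged 2 to 24 hours, that carried an org-1 transgene with green fluorescent protein fused to its C-terminal end. The labels name the antibody in 2 ways, as one against the fluorescent protein in the description and as org-1 in the antibody field, and the first was taken. Per the labels, chromatin was sheared by sonication and the fragment size range was 200 to 800 bp. The 2 libraries are labelled as biological replicates 1 and 2 of 1 group. No second condition was analysed here.

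The deposited peak lists hold, for each region, its position, a signal value, a −log10 q value and the offset of the summit. Per the file descriptions that came with the libraries, the authors made them from alignments of each library together with a control alignment. The aligner and the peak caller are not given in the sources used here. Candidate regions were deposited for each replicate and for the pooled replicates (30000 regions each), and a shorter optimal list was deposited that had been thresholded on the irreproducible discovery rate, a measure of the rank agreement between replicates. The lists exist for the genome builds dm6 and dm3. All results are in dm6 unless dm3 is named, and no coordinate was converted between builds. The signal value is the authors' own and was used to rank and describe regions within a list. The authors' −log10 q values run from 2.71 to 3.78 in the optimal list, and 2995 of its 4434 regions share the highest value, so that this column ranks the strong regions poorly. The files give no read counts, so the depth of each library is unknown and no interval that needs it is given. Intervals of shares of peaks are exact binomial 95% intervals and cover the counting of peaks only.

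Gene models came from Ensembl release 115 (annotation BDGP6.54) and sequence from release 6 of the genome, whose arm lengths hold every dm6 region. The 13945 protein-coding genes on arms 2L, 2R, 3L, 3R, 4 and X were used. A summit was assigned to the first that applied of promoter (within 500 bp of an annotated start of a protein-coding transcript), coding exon, UTR, intron and intergenic sequence. Shares were tested two-sided against 1000 circular shifts of the summits within each arm. Replicates were compared by the share of the 4434 regions of replicate 1 with the highest signal that overlapped a region of the same rank range of replicate 2 by 1 bp or more, one-sided against 1000 circular shifts. Arms were compared by exact binomial tests on arm length.

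Words were searched on both strands within 50 bp of the summit and compared with windows of the same width centred 400 bp to either side. The test was an exact McNemar test against 1 of these flanks chosen at random per peak. For the motifs, the flank share given is the mean of both flanks, so it can differ from the share in the tested flanks. For all words of 6 bases it is the share in the tested flanks. As an alternative the flanks were replaced by random windows matched on GC content in steps of 2%. The p values of the 24 motifs and of all canonical words of 6 bases were each adjusted by the Benjamini-Hochberg method. For 22 gene lists, the number of genes with a summit in the gene or within 5 kb of it was compared two-sided with 10000 random lists, each gene replaced by 1 of the 50 nearest in window length (a permutation test). The lists were those for T-box genes, somatic muscle identity, visceral mesoderm, cardiac and alary muscle, early mesoderm, muscle structure and myoblast fusion. Further lists covered ectoderm segments, neural regulators, neural regulators and neuronal genes, endoderm and gut, trachea and salivary gland, and Hox genes. The neural lists overlap, and neither contains the other. The rest were the Notch, EGFR and FGFR, BMP and Wnt pathways, haemocytes and fat body, germ cells, ribosomal proteins, chemoreceptors and the proteasome. For the closing tests, GC-matched windows were drawn anywhere on the arms. A list of 32 genes taken as highly expressed, outside the ribosomal protein list, was written down before it was tested. Peak strength was compared between sets of regulators by a permutation test with 100000 resamples.

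The tests, the motifs, the gene lists and the rule for naming genes were fixed before the data were examined. For 9 listed symbols the current symbol was looked up afterwards. The rule named org-1, slou, lbe, lbl and tup, the gene with the nearest start to each of the 20 peaks with the highest signal, up to 4 members of each list with the highest signal and up to 3 without a summit (2 of each in lists of over 100 genes), every motif and the 10 words with the lowest p. Not every gene that this rule covers is named. Alternatives covered the overlap rule, the number of peaks, each replicate on its own, the build, the promoter and gene windows, the word, the word window and the reference windows. Leaving out 1 replicate meant using the 4434 regions of the other with the highest signal.

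The statistics were tested on simulated data. On summits shifted to random places no word of 6 bases was called. A T-box core planted in 50 of 4434 summits was found by the test of that word (exact McNemar p = 3.91e-05). The exact McNemar test of all words of 6 bases called 0 of the 2 words of a core planted in 100 summits (lowest Benjamini-Hochberg adjusted p = 0.0709) and both when it was planted in 200, so that it can miss rare words. The simulated summits held no other planted word, so this limit need not hold for the peaks. There GTGCAC was called at 142 summits against 53 GC-matched windows (adjusted exact McNemar p = 3.65e-08). Of 200 random gene lists, 1.5% had a permutation p under 0.05. Computations used Python 3.11 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.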

Results

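Binding of the tagged org-1 protein was mapped in 2 biological replicates of mixed-sex embryos aged 2 to 24 hours. Org-1 is a T-box transcription factor related to vertebrate Tbx1 that acts in founder cells of the somatic and visceral muscles. The optimal peak list held 4434 summits in 4409 distinct regions, 72.0% of which were 456 bp wide. The signal value, as deposited by the authors, ran from 101 to 2560 with a median of 164. Every peak of the optimal list was present unchanged in the pooled candidate list, where the 4434 peaks were also those with the highest signal. Read depth is unknown from these lists. The comparisons below ask how far the replicates share regions, where the peaks lie, which genes they lie at and which sequences they hold.

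The replicates shared most of their strongest regions. Of the 4434 strongest regions of replicate 1, 2778 (62.7%) overlapped a strong region of replicate 2, against a mean of 2.65% and a maximum of 4.04% over the circular shifts (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Regions drawn at random from both candidate lists overlapped in 9.60%. Among the optimal peaks, 3675 overlapped a strong region of replicate 1, 3409 one of replicate 2 and 2729 both, while 79 overlapped neither. Across the 4264 optimal peaks with a candidate region in each replicate, the signal values had a Spearman rho of 0.430 (bootstrap 95% interval 0.402 to 0.455) and a Pearson r of 0.521 on the log2 scale. These are correlations across peaks, which are not independent replicates. The peaks are also those with the highest pooled signal, a selection that lowers a correlation between the replicates, and no value without it was computed.

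The strongest regions of the 2 replicates differed in base composition. The 101 bp around the strongest summits of replicate 1 held 32.4% GC and those of replicate 2 39.6%, beside 42.2% for the chromosome arms. Strong regions of replicate 1 with no counterpart among the strong regions of replicate 2 held 30.1% GC (n = 1656). Strong regions of replicate 2 with no counterpart among those of replicate 1 held 44.7% (n = 1682). The optimal peaks had 34.7% GC (SD 9.12) at the summit and 43.6% in the flanks. With 1 library on each side this difference has no replicate check.

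**Figure D1:**
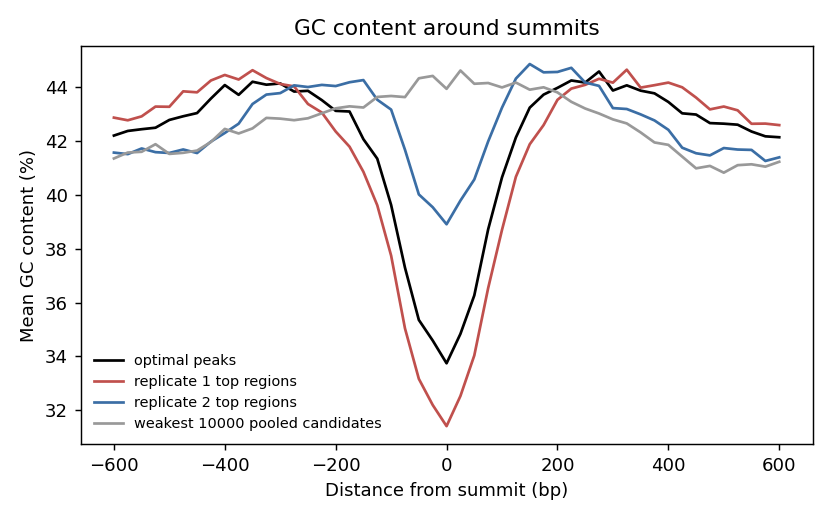
Mean GC content (%) of 25 bp windows against the distance from the summit (bp), for the optimal peaks, the 4434 strongest regions of each replicate and the 10000 weakest pooled candidates. GC content fell to 33.7% at the centre of the optimal peaks, and the fall was deeper in replicate 1 than in replicate 2.

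Summits were more frequent at promoters than in the circular shifts and nearly absent from coding exons, while introns held the most of the full list. Of the 4434 summits, 1668 (37.6%, exact interval 36.2 to 39.1) were within 500 bp of an annotated start, 3.28 times the 11.5% of the circular shifts. Coding exons outside promoters held 6 summits (0.135%), against 14.1% in the shifts. In the regions of replicate 2 alone the coding exon share was 0.631%, and in those of replicate 1 alone 0.113%. UTRs held 57 (1.29%, against 5.16%), intergenic sequence 794 (17.9%, against 30.0%) and introns 1909 (43.1%, against 39.3%). Each of the 5 differences had a two-sided permutation p of 0.001998, the smallest that the shifts can give. Promoter summits lay mostly upstream of the start, 1324 of 1668 (79.4%), at a median position of -130 bp. The promoter share was higher among the 1000 strongest peaks (48.3%) and with replicate 2 alone (40.7%), and in both it exceeded the intron share. The higher intron share did not hold with replicate 2 alone (39.9%, two-sided permutation p = 0.613) or among the 1000 strongest peaks (35.8%, p = 0.0839). Against backgrounds chosen after the data were seen, the intron share lay below that of GC-matched windows (44.02%, Fisher exact p = 0.368) and of the weakest candidates (45.5%, p = 0.00687).

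**Figure D2:**
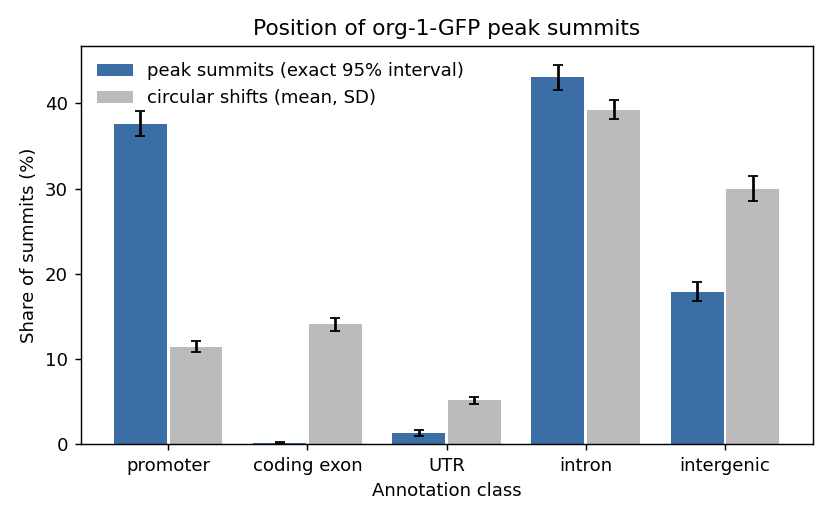
Share of peak summits (%) in each annotation class, with exact 95% intervals, beside the mean and SD of 1000 circular shifts. Promoters held 37.6% of summits against 11.5% in the shifts, and coding exons 0.135% against 14.1%.

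Arm 4, the small and largely heterochromatic chromosome, held 7 summits, or 5.19 per Mb (exact binomial test, Benjamini-Hochberg adjusted p = 3.35e-11). The other arms held 31.6 (3R), 32.0 (2R), 33.0 (3L), 35.5 (2L) and 35.8 (X) per Mb. With replicate 2 alone arm 4 held 1.48 per Mb and with replicate 1 alone 8.16, both past the threshold. The X exceeded its share of the length (19.0% of peaks on 17.6% of the length, exact binomial adjusted p = 0.0410). That call was lost with replicate 2 alone (33.1 per Mb, exact binomial adjusted p = 1) and with replicate 1 alone (35.3 per Mb, p = 0.0603). Arm 2L passed with replicate 2 alone (35.9 per Mb, exact binomial adjusted p = 0.0327) and arm 2R fell below its share with replicate 1 alone (30.4 per Mb, p = 0.0257).

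The strongest peaks lay at genes of varied function. In dm6, the highest signal (2560, with 1632 in replicate 1 and 927 in replicate 2) was in an intron of CG32772 (FBgn0052772) on X from 4910005 to 4910603. The second (2524, with 1360 and 1167) was on 2L from 480814 to 481348, in an intron of ush, which encodes a partner of GATA factors, and 1377 bp upstream of cbt (FBgn0043364), which encodes a zinc finger protein. They were followed by an intron of CG11050 (2446), the promoters of the wing vein gene px (2356) and of Ugalt, which encodes a UDP-galactose transporter (2338), and an intergenic peak nearest to CG4004 (1942). The rest of the 20 strongest were nearest to CG14100, hll, Chro, Lk6, CG13323, CG1888, CG31145, CG42507, PNPase, CG9663, Tina-1, Atf3, HmgZ and Tlk, with signals down to 1383. The peak nearest to CG42507 lay in an intron of Trl, the gene of the GAGA factor. Of these 20 peaks 9 lay in promoters, 8 in introns and 3 between genes, and all 20 were among the 100 strongest regions of each replicate.

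The tagged gene, org-1 (FBgn0021767), carried 2 summits. The stronger lay on X from 8455212 to 8455568, 336 bp upstream of the org-1 start, with a signal of 484 (259 in replicate 1 and 226 in replicate 2), rank 349 of the optimal list. Of the muscle identity genes fixed with it, slou (FBgn0002941) and lbe (FBgn0011278) had no summit in the gene or within 5 kb. The homeobox gene lbl (FBgn0008651) had 1, in an intron on 3R from 21419914 to 21420369, with a signal of 114 (93.3 and 26.8). The LIM homeobox gene tup (FBgn0003896) had 1 within 5 kb (319, with 218 and 95.2), on 2L from 18857666 to 18857901, but this summit lay 92 bp from a start of the neighbouring gene CG10602.

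Within 5 kb, genes of the muscle and mesoderm lists carried summits about as often as genes of the same length, though these lists are small. Among all 13945 genes, 5714 (40.98%) had a summit in the gene or within 5 kb. Of 22 somatic muscle identity regulators 11 had one, where matched random lists had 11.7. The counts were 13 of 23 visceral mesoderm genes (13.2 in matched lists), 13 of 21 cardiac and alary muscle genes (11.5), 10 of 16 early mesoderm genes (8.65), 10 of 18 muscle structural genes (9.33), 8 of 13 myoblast fusion genes (7.30) and 5 of 8 T-box genes (4.19). The Benjamini-Hochberg adjusted permutation p was 1 for each of these 7 lists, over the 22 lists tested. The exact intervals were wide, such as 35.4% to 84.8% for early mesoderm genes. Other settings moved the counts in both directions, and none of the 7 lists passed after adjustment in any. Early mesoderm genes had 13 of 16 with replicate 2 alone (8.75, permutation p = 0.0412, adjusted p = 0.227). T-box genes had 5 of 8 by nearest start (2.46). At own promoters, somatic muscle identity regulators had 1 of 22 (3.60) and cardiac and alary muscle genes 1 of 21 (3.74), but early mesoderm genes 5 of 16 (2.79). The early mesoderm count was above the expected one in every setting, up to 1.82 times among the 1000 strongest peaks. Single members had strong peaks. Mef2, the myocyte enhancer factor gene, had 7 summits in its window. The highest of them (1219, rank 28, 660 and 560 in the replicates) lay on 2R from 9959692 to 9960123. It was in the promoter of the neighbour Pal1 and 1057 bp upstream of the Mef2 start. Summits within 500 bp of their own start were found at Poxm (368), tin, the heart and visceral mesoderm homeobox gene (385), Msp300 (574) and sls, which encodes a titin-like protein (366). Intronic summits lay in kirre, a myoblast fusion receptor gene with 20 summits in its window (509), in zfh1 (445) and in pnt (338), and a summit lay 1364 bp upstream of the forkhead gene bin (389). No summit was found at Kr, Ptx1, Six4, Alk, eve, bap, Him, lmd, Mhc, Prm or Mlp60A. Among T-box genes, Doc2 and Doc3 shared an intergenic summit (256) and bi had an intronic one (159), while H15, mid and byn had none.

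Ribosomal protein genes carried summits more often, and chemoreceptor genes less often, than matched genes. Of 88 ribosomal protein genes 69 had a summit (78.4%, exact interval 68.4 to 86.5) against 31.01 in matched lists, and of 119 odorant and gustatory receptor genes 20 had one (16.8%, 10.6 to 24.8) against 43.7 (adjusted permutation p = 0.00220 for both, from p = 0.0002, the smallest that 10000 lists can give). Among the 4 members with the highest signal, the summits lay 43 bp inside RpL7 (771), 2 bp inside RpS27 (768) and 19 bp upstream of RpL14 (638), whereas that near RpS7 (682) lay 384 bp from the start of CG9743, and RpL10, RpL10Aa and RpL15 had no summit. With summits within 500 bp of an own start the counts were 58 of 88 ribosomal protein genes (16.4 in matched lists) and 0 of 119 receptor genes (12.3). Near the receptor genes Gr5a (485) and Or85f (383) the nearest start was that of Tre1 and RpL34b. Neighbouring receptor genes could share a summit, and Gr64d, Gr64e and Gr64f had the same strongest signal (124). The matched lists draw each gene separately, so the interval and p for the receptor genes may be too narrow. The lower count of receptor genes did not pass with the 1000 strongest peaks (6 against 14.2, 0.422 times, adjusted permutation p = 0.126) or with peaks given to the gene of the nearest start (6 against 15.2, 0.394 times, p = 0.103), where the ratios were no nearer to 1 than the 0.458 of all peaks. The proteasome subunit genes, another household group, had 16 of 38 (14.3 in matched lists, adjusted permutation p = 1).

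None of the other lists passed the threshold after adjustment. BMP pathway genes had 11 of 12 with a summit, among them gbb, Dad, Mad and Med (6.83 in matched lists, permutation p = 0.0208, adjusted p = 0.117), and germ cell genes 8 of 9, among them bgcn, bam, aub and vas (4.29, p = 0.0212, adjusted p = 0.117). The summit near bam was that of RpS27, that near aub lay 20 bp from the start of RpL9, and gbb and bgcn shared a summit 109 bp from the start of eIF6. The direction of both lists turned with some other windows. Germ cell genes had 2 of 9 within 2 kb (2.99 in matched lists) and 1 of 9 by nearest start (1.92), but 2 of 9 at own promoters (1.11). BMP pathway genes had 1 of 12 at own promoters (2.40), but 10 of 12 within 2 kb (5.58) and 8 of 12 by nearest start (4.11). The summit near Med lay 2 bp from the start of Mnat9 and that near vas in an intron of ck. Higher than the matched mean were also the EGFR and FGFR pathway genes (11 of 14, 8.46), with spi (717), aos (617), aop (423) and vn (381), the Notch pathway genes (9 of 14, 6.42), with N (627), the Wnt pathway genes (8 of 12, 7.37), with fz (502) and dsh (507, in an intron of CG1737), and the endoderm and gut regulators (6 of 9, 5.09), with fkh (719). Tracheal and salivary regulators had 6 of 11 (6.10). Lower were Hox genes (3 of 8, 5.36), haemocyte and fat body genes (4 of 13, 6.96) and ectoderm segment regulators (4 of 16, 7.74). So were neural regulators (5 of 19, 8.77) and the overlapping list of neural regulators and neuronal genes (7 of 21, 10.3). Adjusted p ranged from 0.415 to 1 over these lists.

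**Figure D3:**
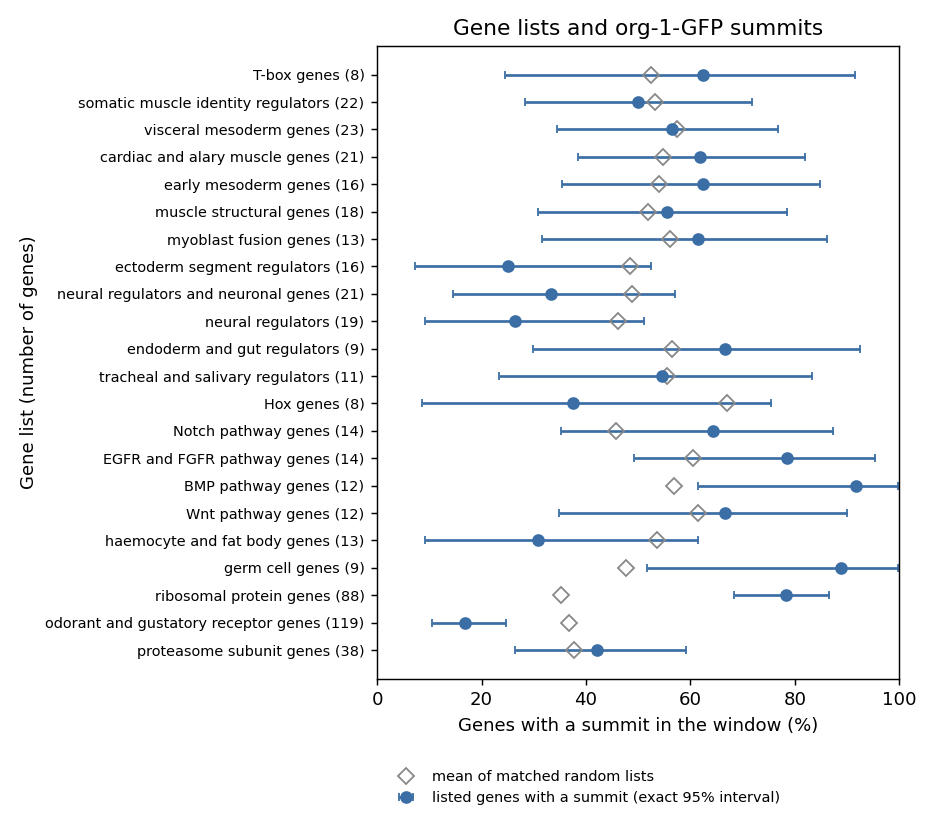
Share of genes (%) with a summit in the gene or within 5 kb, for each gene list with its number of genes, with exact 95% intervals, beside the mean of 10000 random lists matched on window length. Ribosomal protein genes (78.4%) lay above their matched lists and odorant and gustatory receptor genes (16.8%) below.

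Regulators of mesoderm and muscle were compared with regulators of ectoderm and nervous system by the signal of their strongest summit. A summit was found at 26 of 46 mesoderm and muscle regulators and at 9 of 34 ectoderm and neural regulators. The mean log2 signal was 7.91 (SD 0.74) and 7.51 (SD 0.85), a difference of 0.39 (SE 0.32) that did not pass the test (two-sided permutation p = 0.197). The strongest in the second set were slp2 (656), ptc (315) and pros (201), whereas en, ftz, SoxN, ac and ase had no summit. The neuronal gene elav, which was not part of this set, had a summit 271 bp upstream of its start (781, with 481 and 299 in the replicates). The summit counted for ptc lay in an intron of Acsl and that for pros 53 bp from the start of mgr. With a window of 2 kb the difference was 0.79 (23 and 7 genes, permutation p = 0.0248).

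The T-box core was not more frequent at summits than beside them. The word AGGTGTG was present within 50 bp of 26 summits (0.586%, exact interval 0.383 to 0.858) and in 0.823% of flanks (exact McNemar p = 0.366, adjusted p = 0.488 over 24 motifs). In GC-matched windows its share was also 0.586%. Against 10 sets of such windows, chosen after the data were seen, it was 0.949 times as frequent at the optimal summits, 1.08 times in replicate 1 and 1.34 times in replicate 2 (Fisher exact p = 0.920, 0.675 and 0.0812). The longer word AGGTGTGA was present at 7 summits (0.158%, against 0.124% of flanks, exact McNemar p = 0.549). It was also above flanks in replicate 1 (0.226% against 0.135%, exact McNemar p = 0.180) and replicate 2 (0.226% against 0.113%, p = 0.0923). Its share of GC-matched windows was lower for the optimal peaks (0.0902%) and replicate 1 (0.180%) and higher for replicate 2 (0.271%). None of these differences passed. For the core AGGTGTG the direction turned with replicate 2 alone (0.970% against 0.710% of flanks, exact McNemar p = 0.201). In 4 equal groups of peaks from the strongest to the weakest, the core was present at 5, 6, 6 and 9 summits, and the mean signal percentile of peaks with it was 44.9 against 50.03 without (permutation p = 0.370).

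The other motifs differed between summits and flanks in both directions, and many of these calls changed with the reference or the replicate. More frequent at summits than in flanks were the forkhead motif (24.9% against 14.02%), the TATA box (20.1% against 10.2%), the homeodomain word TAATTA (8.95% against 5.85%), the Pbx/Hox motif (7.89% against 5.83%), E-box CATATG (4.44% against 3.21%), GATA (3.90% against 2.65%) and DREF (0.857% against 0.192%), with adjusted p from 3.97e-39 to 0.00358. Less frequent were SMAD (0.474% against 2.26%), GAGA (1.38% against 3.26%) and the E-boxes CAGCTG (3.32% against 4.62%), CAGGTG (2.62% against 3.98%) and CACGTG (0.902% against 1.52%). With replicate 2 alone, only forkhead (21.4% against 15.2%, adjusted exact McNemar p = 3.51e-14) and DREF (0.677% against 0.338%, p = 0.0346) of these 12 motifs still passed. The lost calls included those of the homeodomain word (6.29% against 6.71%, adjusted exact McNemar p = 0.215), the TATA box (13.9% against 11.9%, p = 0.0859), GATA (3.50% against 3.01%, p = 0.215), Pbx/Hox (6.68% against 6.09%, p = 0.215), SMAD (1.44% against 1.84%, p = 0.215) and GAGA (2.503% against 3.02%, p = 0.371). E-box CATATG passed with neither replicate alone (adjusted exact McNemar p = 0.0922 and 0.0927), and the E-boxes CAGCTG, CAGGTG and CACGTG did not pass with replicate 2 alone (p = 0.522, 0.371 and 0.371). Against GC-matched windows 3 of the 7 higher motifs still passed. They were forkhead (20.2% of windows, adjusted exact McNemar p = 2.53e-06), GATA (2.64%, p = 0.0117) and E-box CATATG (3.20%, p = 0.0257), each of which also passed with either replicate alone, forkhead with replicate 1 at p = 0.0491. DREF did not pass (0.857% against 0.406%, adjusted exact McNemar p = 0.0627) but was still 2.11 times as frequent as in these windows, whereas the ratios of the TATA box, Pbx/Hox and the homeodomain word were 1.03, 0.946 and 0.923. Among the optimal peaks no motif passed as lower than in these windows. TEAD was at 3.36% against 4.01% there (adjusted exact McNemar p = 0.398) and passed as lower with replicate 1 alone (3.0% against 4.08%, adjusted exact McNemar p = 0.0416) and replicate 2 alone (3.45% against 4.74%, p = 0.0110), and Pbx/Hox with replicate 2 alone (6.68% against 8.19%, p = 0.0269). Some motifs that were less frequent than in flanks were more frequent than in GC-matched windows. E-box CAGCTG was so with replicate 1 alone (3.0% against 1.85%, adjusted exact McNemar p = 0.00615) and replicate 2 alone (4.67% against 3.0%, p = 0.000189), and GAGA (2.503% against 0.992%, p = 7.09e-07) and E-box CACGTG (1.22% against 0.699%, p = 0.0457) with replicate 2 alone. These did not pass among the optimal peaks. Between 50 and 150 bp from the summit, a window chosen after the data were seen, E-box CAGCTG was more frequent than between 350 and 450 bp (10.7% against 8.98%, adjusted exact McNemar p = 0.0163) and ETS less frequent (0.338% against 1.11%, p = 6.97e-05). There forkhead, the TATA box, the homeodomain word, DREF and GATA were also higher, SMAD and E-box CAGGTG were also lower, and GAGA, E-box CACGTG, E-box CATATG and Pbx/Hox did not pass. Zelda, MEF2, NK2, TCF, ETS, TEAD, M1BP, BEAF, Su(H) and the control word passed against neither reference among the optimal peaks, though Su(H) was lower than in flanks with replicate 2 alone and TEAD with replicate 1 alone (adjusted exact McNemar p = 0.00426 and 0.00954).

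Among all words of 6 bases, 492 were more frequent at summits than in flanks and 953 less frequent (Benjamini-Hochberg adjusted exact McNemar test). The 10 words with the lowest p held only A and T. They were AAATAT (33.3% of summits against 15.3% of flanks), TTAAAA, TAAATA, ATTTTA, ATTTAA, AATATA, ATATTA, TATTAA, AAAATA and TTTAAA, present 1.71 to 2.56 times as often. Words that were more frequent held 1.55 G or C bases on average and those less frequent 3.93. With replicate 2 alone, whose summits were less AT-rich, 243 words were more frequent and 289 less frequent, and against GC-matched windows 92 and 78.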

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

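The composition and position of the regions described here were computed after they had been found. In the dm3 candidate lists, whose sequences outside the main arms entered no comparison of composition, class or genes, 59 candidate regions of replicate 1 and 10 of the pooled replicates lay on sequences outside the 6 main arms, each count above the limit of 3 set for data without a control. Replicate 2 had 1 such region, and the difference between the replicates was not tested. Those of replicate 1 lay on 3LHet (20), 2RHet (13), XHet (13), 3RHet (11) and U (2), and none reached the dm3 optimal list. The highest signal among them was 53.3, at rank 4916 of 30000.

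The q value column was not used to rank or select regions, and some regions that reached its lowest value in 1 replicate had no overlapping optimal peak. These were 44 of 2455 regions (1.79%) in replicate 1 and 43 of 1931 (2.23%) in replicate 2. Their summits held 30.8% GC in replicate 1 and 49.2% in replicate 2, and 63.6% and 60.5% of them lay in promoters. Of them, 34 and 35 overlapped a pooled candidate region. All 44 and 43 were among the 4434 strongest regions of their replicate, and so were part of the comparisons of the replicates.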

How the results depend on the processing

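Of the alternative values for 23 results, 96 kept their direction and their side of the threshold or stayed within the range set for a value without a test, 12 moved, 8 no longer passed, 1 newly passed and 10 changed direction. Added after seeing the data were the promoter share against GC-matched windows and the weakest candidates, the peaks found in both replicates, AGGTGTGA with a mismatch, the windows 50 to 150 bp from the summit, the 10 sets of GC-matched windows and the comparison of regulator sets with matched genes. The promoter share stayed above its reference in every alternative run, from 26.9% within 250 bp to 48.3% among the 1000 strongest peaks, and the replicate overlap stayed between 50.6% and 63.2%. The rank correlation was 0.364 among the 1000 strongest peaks, which are selected more strictly on pooled signal. The number of arms past the threshold was 2, and 4 among the 2217 strongest peaks, where 2L lay above and 3R below its share. For the X the values without 1 replicate were 33.1 and 35.3 per Mb, the lower one below the share of length. The intron share was 35.8% among the 1000 strongest peaks, below the shifts.

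The T-box core share passed the threshold in no alternative. It lay above its reference without replicate 1 (range without 1 replicate 0.609% to 0.970%), in each replicate alone against 10 sets of GC-matched windows (0.609% against 0.564%, and 0.970% against 0.724%), for AGGTGTGA (0.158%) and 50 to 150 bp from the summit (1.74% against 1.65%, exact McNemar p = 0.807). The percentile difference of peaks with the core was 19.1 among the 1000 strongest peaks and 1.88 within 100 bp, neither past the threshold. More frequent words of 6 bases numbered 268 among the 1000 strongest peaks, 243 to 490 without 1 replicate and 92 against GC-matched windows. Gene lists past the threshold numbered 1 with the 1000 strongest peaks, 1 with the nearest start and 5 with the unmatched Fisher exact test, where the BMP, germ cell and EGFR and FGFR lists were added, the germ cell list being below matched lists within 2 kb and by nearest start. The regulator strength difference was 0.79 within 2 kb. Ectoderm and neural regulators with a summit were 0.558 times as many as matched genes within 5 kb, 1.49 times by nearest start and 0.505 to 0.806 times without 1 replicate. The 1000 strongest peaks left too few genes for the strength difference. Apart from the smaller number of peaks in the stronger subsets, the cause of these changes was not tested. No paired analysis was possible because the series holds 1 group. Depth is unknown and limits could not be set from it.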

Other observations

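The words beside the summits, their strand, the 10 sets of GC-matched windows, the mismatch search and the comparison of regulator sets with genes of matched length were examined only after the data had been seen, and so were the tests marked as such below. Of the ectoderm and neural regulators 9 of 34 carried a summit, against 16.1 genes of the same length (permutation p = 0.0160, not adjusted), whereas the count of mesoderm and muscle regulators was close to theirs, 26 of 46 against 24.8 (p = 0.823). The first comparison did not pass within 2 kb (7 of 34 against 11.9, permutation p = 0.0860) or without replicate 1 (13 against 16.1, p = 0.341). Its direction turned when peaks were given to the nearest start (13 against 8.72, permutation p = 0.114), and it passed without replicate 2 (8 against 15.8, permutation p = 0.00920).

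Words with CAGTG stood out once AT content was matched. ACAGTG was present at 321 summits and 131 GC-matched windows, and ACACTG at 310 and 138 (Benjamini-Hochberg adjusted exact McNemar p = 3.85e-17 and 3.83e-14). They were most frequent beside the deposited summit. In windows of 51 bp, ACAGTG was present in 3.11% at the centre, 6.57% at 75 bp to either side and 1.87% at 400 bp. The same held in replicate 1 (2.59%, 6.47% and 2.22%) and replicate 2 (3.45%, 5.71% and 1.97%). Between 50 and 150 bp from the summit it was present at 884 peaks, or 19.9%, against 7.87% between 350 and 450 bp, the lowest p of all words there, followed by AGTGTA and ACACTG. Its strand differed between the sides, with 354 peaks carrying it as written and 147 in reverse complement on the left, and 147 and 395 on the right (Fisher exact p = 4.43e-46). A peak with both orientations or with the word on both sides entered more than 1 of these counts. The counts are therefore not independent, and this p is approximate. Of the peaks, 139 had it on both sides, where 58.9 would if the sides were independent and all peaks alike.

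A hypothesis is that a sequence with CAGTG marks many of these regions. It was tested against a preference of 1 library and against initiator sequences of promoters. In strong regions of either replicate that overlapped no strong region of the other, ACAGTG exceeded GC-matched windows. The lower ratio was 2.48, so the excess was not confined to the strong regions of 1 library. Such regions can still be weaker candidates in the other library, so a preference of 1 library is not excluded. At summits away from promoters ACAGTG was 2.69 times as frequent as in GC-matched windows, which argues against initiator sequences as the cause. The M1BP word, which shares the bases ACACT, was present at 10 of the 310 summits with ACACTG. The distance from the summit may come from how the deposited summits were placed rather than from the sequence, which was not tested, nor was which protein may bind these words.

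The near absence of summits from coding exons was weighed against base composition, and the test on replicate 2 was chosen after the result was seen. Random windows matched on GC content lay in coding exons in 5.62% (exact interval 4.96 to 6.33), between the 0.135% of summits and the 14.1% of the shifts, so that AT-rich sequence may account for part of the deficit and not for all of it. In replicate 2, whose summits were less AT-rich, the share was 0.631% (interval 0.420 to 0.911), below the lowest of the shifts (11.95%), which argues against a preference of replicate 1 as the cause. What else keeps summits out of coding exons stays open, and no biological explanation was tested.

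The lack of an excess of the T-box core was weighed against AT-rich summits, dilution by weak regions (both tests chosen after the result was seen) and a word that is too strict. The summit share was 1 times that of GC-matched windows, and 0.949 times that of 10 such sets (odds ratio interval 0.608 to 1.42), which argues against an excess of 1.5 times hidden by AT content among the optimal peaks, but the ratio was 1.08 in replicate 1 (odds ratio interval 0.697 to 1.61) and 1.34 in replicate 2 (0.952 to 1.85), which leaves it open for each replicate alone. Among the 1000 strongest peaks the share was 0.4% (4 peaks, interval 0.109 to 1.02), against 0.8% of flanks and 0.46% of 10 GC-matched sets (odds ratio interval 0.227 to 2.39), too few peaks to exclude dilution. With up to 1 mismatch in AGGTGTGA the share was 4.60%, against 4.06% of GC-matched windows (exact McNemar p = 0.233) and 4.01% of 10 sets (Fisher exact p = 0.0610), but 4.75% of flanks (exact McNemar p = 1), so that whether looser sites are in excess stays open. Indirect binding could not be tested, and no biological explanation was.

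The summits at ribosomal protein genes were weighed against high expression, neighbouring genes and household genes in general, the last chosen after the result was seen. With summits within 500 bp of an own start the count was 3.53 times that of matched lists, which argues against neighbours as the cause. The share at proteasome subunit genes was 42.1% (interval 26.3 to 59.2), below the interval of the ribosomal protein genes, so this household group did not share the pattern. As 1 list of 38 genes it cannot speak for household genes in general. Of 32 other genes taken as highly expressed, listed before the test, 20 had a summit against 13.97 in matched lists (permutation p = 0.0468, not adjusted). These genes leave high expression open as part of the pattern, though expression was not measured here. Their share was lower than that of the ribosomal protein genes, which passed the test at own starts (Fisher exact p = 0.0358) and not within 5 kb (p = 0.0994), so that high expression may account for the pattern in part and a signal that follows transcription stays open.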
